A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

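Total RNA of one time course of budding yeast was measured by RNA sequencing. Per the labels, cells of the laboratory strain BY4741, carrying a YFP reporter driven by the PHO84 promoter and overexpressing the phosphate transporter gene PHO90, were grown with high phosphate, washed and moved to medium without phosphate. They were sampled every 15 min up to 360 min. There were 25 libraries, 1 per time point: 1 from the high-phosphate culture at 0 min and 24 from the medium without phosphate. The promoter used for the overexpression is not given in the sources used here. RNA was extracted in a 96-well format with a column kit after lyticase treatment, and cDNA was sequenced on an Illumina HiSeq instrument, per the labels' protocols.

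Reads were aligned with Bowtie to genome build R64, per the submitters' processing notes. The read counter, the annotation and the use of strand are not given in the sources used here. The deposited table holds log2 values for 6650 named genes, plus 51 entries without a name that held no value. The design text describes expression normalized to the first time point, whereas the deposited values were not ratios: 2 raised to the deposited log2 values summed to 1000000 in every library over the genes with a value, so they were taken as log2 RPM. No library listed a gene below 15 reads, and entries under that floor were missing. With a tolerance of 0.02 reads, 93.6% to 94.4% of the values of a library came out as whole reads, and the rest were fractional. Because of this fractional part the values were kept as log2 RPM and no count model was fitted.

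Reads in listed genes ranged from 450744 in the 15 min library to 2271193 in the 90 min library, with a median of 1005706. The median was 1382080 for the early, 1010602 for the middle and 612972 for the late libraries, so the floor in RPM was higher late than early. Of the named genes, 5383 had a value in at least 1 library and 3255 in all 25. Gene names were matched to the R64 annotation of the reference used here, 5917 by symbol or locus and 47 by synonym. Of the 686 unmatched names, 148 had a value. One name occurred more than once.

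With no replicate libraries, time points in fixed windows stood in for replicates: early (15 to 120 min), middle (135 to 240 min) and late (255 to 360 min), 8 libraries each. The spread within a window holds both library noise and change inside the window. All libraries came from one course, with nothing in the labels pointing to separate cultures, so the p-values measure only the spread between these libraries and assume that they are independent. Around a smooth trend the median residual SD was 0.227 (log2), and the median correlation of successive residuals was 0.025.

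Genes with a value in at least 20 of the 24 no-phosphate libraries, no value repeated in more than a share of 0.5 of them and a mean of at least 1 RPM were tested, which kept 4343 genes and left 1040 listed genes untested. The mean minimum removed none of them. Window means were compared with limma 3.58.1 in R 4.3.3 (moderated statistics with trend and robust estimation) on the deposited log2 values, with no pseudocount. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. A natural cubic spline of time with 3 degrees of freedom was tested with limma's F statistic, with a fitted range of at least 1 for a call. All tests were two-sided.

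Gene lists (29) were written before the data were examined, as were the windows, the tests, the alternatives other than those named as added, and the rule for genes to name. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 25 lists. Camera with an estimated correlation and fry were run on the 3275 genes without a missing value in the 24 libraries, and the estimated correlation includes trends shared by members inside a window. The rule named PHO90, all members of the PHO regulon and phosphate signalling lists, the 10 largest called changes in each direction late minus early, the 5 largest for each of the other comparisons, and up to 3 members of every other list; 1 gene that it named is not reported here. The list of cytosolic ribosomal proteins was a name pattern, and it also took in RPP1, which encodes a subunit of RNase P.

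Half-rise times were the first crossing, by linear interpolation, of the level midway between the 0 min value and the maximum of a running median of 3 time points. Intervals (95%) came from 1000 resamplings of residuals around that running median. Such a residual is 0 wherever 3 successive values rise or fall in order, so these intervals understate the scatter between libraries. The 0 min library was compared with the median of the early window with no test, for genes with a value in at least 6 early libraries. List medians were then set among 10000 random lists of like size and expression. Intervals for single-library values were exact Poisson intervals (95%) and cover counting error only.

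The steps were tested on simulated data. For late minus early, over 4145 genes, 76.1% of genes changed by 1.5 (log2), 74.6% of those changed by 2 and 59.1% of those changed by 3 were recovered. All of the losses came from the listing filter, since 100% of changed genes past it were recovered, and 0 unchanged genes were called. Simulated levels were flat inside a window, with a scatter of 0.227 (log2) and no deviation shared within a library. Real levels also changed inside windows, so these shares are not error rates of the real tests. The time trend step called 6 unchanged genes. In the list step 1 of 1 moved lists and 0 of 24 unmoved lists were called. Simulated genes varied independently, whereas the estimated correlation was 0.688 in the PHO regulon and 0.906 in ribosomal proteins. The simulation therefore does not show how the list step behaves with correlated genes. Midpoints simulated at 45, 90 and 150 min were estimated at 48.6, 92.1 and 151.6 min.

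Alternatives covered scaling, gene filters, limma settings, library weights, every second time point, other windows, other size limits and leaving out each library. Added after the data were seen were missing entries set at the floor, scaling to reads outside the ribosomal protein list, fits without the 15, 345 and 360 min libraries, and alternatives for the 0 min comparison. The pseudocount and count-model alternatives did not apply to log2 values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Coordinates are R64 and 1-based.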

Results

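The series followed the transcriptome of budding yeast that overexpressed PHO90, a low-affinity phosphate transporter gene, as cells were moved from high phosphate to medium without phosphate. One library was made at 0 min in high phosphate and 24 libraries were made between 15 and 360 min after the move, at intervals of 15 min. Depth ranged from 450744 to 2271193 reads in listed genes. Levels are log2 RPM (reads scaled to a library total of 1000000), and window values are means ± SD over the 8 libraries of the early (15 to 120 min), middle (135 to 240 min) or late (255 to 360 min) window. Libraries without a value for a gene were left out of its means.

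PHO90 (YJL198W, chromosome X, 60844 to 63489) was among the abundant transcripts in every library, from 1636 RPM at 0 min (1595 reads, exact Poisson 95% interval 1557 to 1718 RPM, counting error only) to 5413 RPM at 315 min. Its level was 10.68 at 0 min, 11.24 ± 0.14 in the early, 11.81 ± 0.22 in the middle and 12.19 ± 0.19 in the late window (SD, n = 8 each). The late minus early difference of 0.94 (SE 0.12, limma adjusted p = 1.16e-07) lay under the size limit of 1 and was not called. The other low-affinity transporter genes were far lower: PHO87 reached 5.76 ± 0.17 and PHO91 6.5 ± 0.28 in the late window. PHO90 passed the size limit without the 15, 345 and 360 min libraries, at 1.00. Scaled to reads outside ribosomal protein genes, its difference was 0.48.

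**Figure D1:**
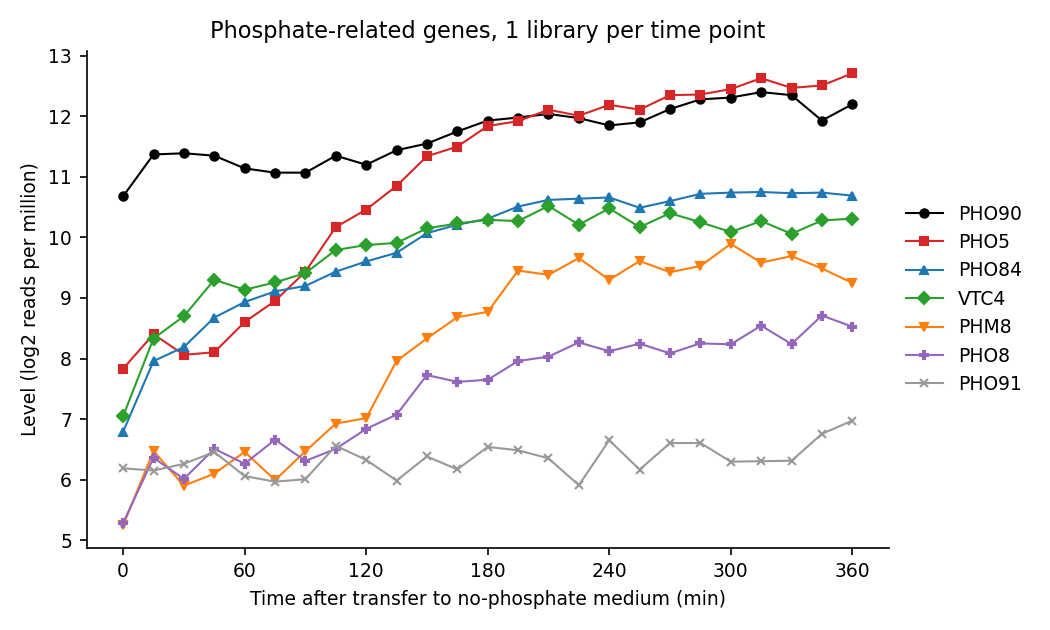
Levels (log2 RPM, y axis) of 7 phosphate-related genes against time after transfer (min, x axis), 1 library per point. PHO90 starts at 10.68 and PHO5 at 7.83, and PHO5 averages 12.45 in the late window.

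The first comparison asked how the late window of phosphate withdrawal differed from the early one. Nearly all ribosomal protein genes were lower (135 of 137), and most genes of the PHO regulon (16 of 19), stress protection (35 of 37), reserve carbohydrates (13 of 15) and autophagy (11 of 15) were higher. Of these lists, ribosomal proteins alone stood apart from other genes with an estimated correlation. Of 4343 genes, 599 were higher and 148 lower. The median tested gene was itself 0.45 higher (log2) late than early, while the share of reads in ribosomal protein genes fell, so changes are also given relative to this shift. With each library centred on its median, 181 genes were higher and 199 lower. Scaled to reads outside ribosomal protein genes, an alternative added after the data were seen, 201 were higher and 191 lower. The 15 and 345 min libraries differed most from the library before them (SD of the log2 change over genes 0.641 and 0.533). The 360 min library did not (0.35), but its ribosomal protein share was like that at 345 min. The library before 15 min was the high-phosphate one at 0 min, so its 0.641 also holds the change of medium. From 15 to 30 min the SD was 0.377. Without the 15, 345 and 360 min libraries the counts were 660 and 157.

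The PHO regulon, the genes driven by the Pho4 transcription factor when phosphate is scarce, rose. Of 19 tested members 16 were higher and 0 lower, 16 also when adjusted over the list alone. The median difference was 1.57, which is 1.11 above that of all genes (camera adjusted p = 6.09e-07; adjusted p = 0.588 with an estimated correlation). The secreted acid phosphatase gene PHO5 rose from 9.02 ± 0.92 to 12.45 ± 0.19 (SD, n = 8), a 10.8-fold difference (log2 3.43, SE 0.28, limma adjusted p = 1.82e-10). PHM8, which encodes a nucleotide phosphatase, was 8.83-fold higher, the sodium-phosphate cotransporter gene PHO89 7.35-fold and PHM6 6.60-fold. PHO84, the high-affinity phosphate transporter gene (chromosome XIII, 24037 to 25800), was 3.47-fold higher. PHO84 lies within an annotated transcript of the opposite strand, and since the use of strand is not known its reads may include that transcript. PHO11 and PHO12, near-identical acid phosphatase genes whose reads cannot be separated with certainty, were 4.26-fold and 3.44-fold higher. GDE1, PHO8, HOR2, VTC1, DDP1, PPN1, PHO81, VTC3 and VTC4 were higher by 4.54-fold to 2.01-fold. PHO86, SPL2 and VTC2 differed by 0.75, 0.98 and 0.99 (log2) and were not called. VTC4 lay at the limit and was lost without any one of the 15, 30, 60, 270, 315, 345 or 360 min libraries (0.88 to 0.998). Without single libraries SPL2 (60, 75, 90, 105, 120 or 360 min; 1.01 to 1.11) and VTC2 (90, 105 or 120 min; 1.02 to 1.06) passed it. Scaled to reads outside ribosomal protein genes, 11 of the 19 were called, and without the 3 libraries 15. GIT1, the glycerophosphoinositol transporter gene, had no value in any early library and one in all 8 late ones, at least 3.64-fold higher than the floor. PHM7 was listed in 4 libraries and CTF19 in 0.

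Of 10 tested genes of low-affinity transport and phosphate signalling, 3 were higher and 0 lower (camera adjusted p = 0.0124; adjusted p = 0.588 with an estimated correlation). The inositol pyrophosphate kinase gene KCS1 was higher by 2.0 (log2, SE 0.17, limma adjusted p = 1.75e-10), VIP1 was 2.22-fold and the Pho85 cyclin gene PHO80 2.07-fold higher. PHO80 lay near the floor, with 15 reads at 330 min and no value at 15 or 345 min. PHO2 had no value at 15, 255, 330 or 345 min. The window means of both leave out values under the floor. PHO80 fell short of the limit without the 90, 120 or 315 min library (0.97, 0.98 and 0.92), and with libraries centred on their median KCS1 alone of the 10 was called. PHO4 differed by 0.96 (1.03 and called without the 255 min library), PHO87 by 0.94, PHO2 by 0.89, PHO85 by 0.81, SYG1 by 0.77 and PHO91 by 0.28 (log2), none of them called; PHO91 was 0.21 lower once libraries were centred.

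Cytosolic ribosomal protein genes fell together. Of 137 tested, 135 were lower and 0 higher, with a median difference of -1.93, or 3.81-fold lower (camera adjusted p = 1.85e-150; adjusted p = 0.0458 with an estimated correlation, the only list called with one). RPL15B (0.36) and the RNase P gene RPP1 (0.06) did not pass the limit for a call. RPL8A was 6.27-fold lower, from 9.59 ± 0.08 to 6.94 ± 0.35 (SD, n = 8; limma adjusted p = 3.29e-09). RPL9A, RPS22A, RPL26B, RPS31, RPS27B, RPP2A, RPS18B, RPL33B and RPS9B were 5.52-fold to 4.64-fold lower. Many of these are members of nearly identical gene pairs, so the value of a single copy is uncertain. The share of reads in the list was 40.1% at 0 min, 34.3% ± 1.98 early, 16.8% ± 8.03 middle and 9.45% ± 2.11 late (SD, n = 8). It stood at 6.80% at 300 min and at 11.2% and 11.1% at 345 and 360 min. Without the 15, 345 and 360 min libraries 135 members were again lower.

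**Figure D2:**
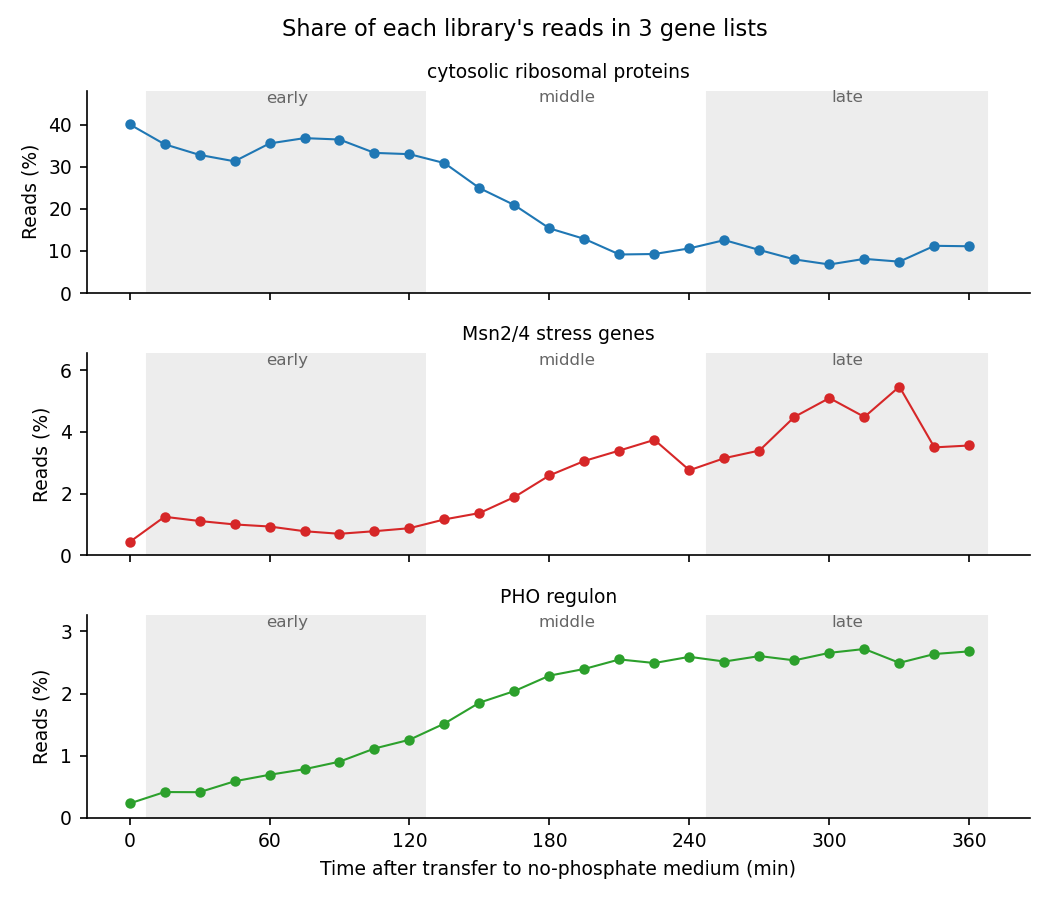
Percent of each library's reads (y axes, starting at 0) in 3 gene lists against time after transfer (min, x axis), with the early and late windows shaded and 1 library per point. The ribosomal protein share goes from 40.1% at 0 min to 6.80% at 300 min, while the PHO regulon share goes from 0.231% to 2.72% at 315 min.

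Genes induced by the stress factors Msn2 and Msn4 rose. Of 37 tested, 35 were higher and 0 lower, with a median of 1.92, 1.46 above all genes (camera adjusted p = 6.09e-07; adjusted p = 0.588 with an estimated correlation). The small heat shock protein gene HSP26 was 18.4-fold higher, from 6.02 ± 0.27 to 10.22 ± 0.62 (SD, n = 8; limma adjusted p = 4.61e-09), GND2 13.9-fold, PAI3 12.2-fold and the catalase gene CTT1 12-fold. YGP1 differed by -0.21 and TMA10 by 0.08, and neither was called. Scaled to reads outside ribosomal protein genes, 27 members were called, and without the 3 libraries 34.

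Reserve carbohydrate genes followed, with 13 of 15 higher and 0 lower (median 1.45, camera adjusted p = 0.00488; adjusted p = 0.664 with an estimated correlation). GPH1, glycogen phosphorylase, was 11.4-fold higher, the glycogen branching enzyme gene GLC3 6.06-fold and PGM2 6.03-fold. Of 15 autophagy genes 11 were higher and 0 lower (median 1.19, camera adjusted p = 0.000751; adjusted p = 0.588 with an estimated correlation), among them ATG8 (4.87-fold), ATG22 (4.68-fold) and ATG34 (4.06-fold). Scaled to reads outside ribosomal protein genes, 7 reserve carbohydrate and 7 autophagy genes were called.

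Of 33 genes of the respiratory chain and ATP synthase 19 were higher and 0 lower (median 1.06, camera adjusted p = 3.5e-07; adjusted p = 0.588 with an estimated correlation). INH1, an inhibitor of the ATP synthase, was 4.59-fold higher, QCR10 2.90-fold and CYT1 2.83-fold. Only 4 members were called when scaled to reads outside ribosomal protein genes. In the TCA cycle 7 of 17 were higher, with SDH4 at 3.30-fold, LSC2 at 2.52-fold and MDH1 at 2.37-fold (camera adjusted p = 0.0341; adjusted p = 0.664 with an estimated correlation), against 1 of 17 with that scaling. The camera adjusted p of the TCA cycle was 0.0508 without the 15, 345 and 360 min libraries. Glycolysis and fermentation was not called as a list (camera adjusted p = 0.238), although 5 of 19 members were higher, led by TDH1 (9.17-fold), ENO1 (5.80-fold) and the minor pyruvate kinase gene PYK2 (2.90-fold).

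Of 17 methionine and sulfur genes 2 were lower and 0 higher, with a median difference of -0.12, and at an unadjusted p under 0.05 limma had 5 lower and 4 higher. The list lay below other genes (camera adjusted p = 1.59e-05; adjusted p = 0.341 with an estimated correlation). The S-adenosylmethionine synthetase gene SAM1 was 2.85-fold and MET14 2.38-fold lower, and CYS3 differed by -0.96, just under the limit. With libraries centred on their median, 5 of the 17 were called lower. Of 74 ribosome biogenesis genes limma called 0 in either direction (5 higher and 5 lower at an unadjusted p under 0.05), while the list as a whole lay below other genes (median -0.03, camera adjusted p = 2.96e-08; adjusted p = 0.698 with an estimated correlation). UTP22, NOP1 and SPB4 differed by -0.80, -0.65 and 0.60. With scaling to reads outside ribosomal protein genes, 4 members were called lower. Without the 15, 345 and 360 min libraries the median was -0.32 and 2 members were called lower; the list held 2.11% and 1.65% of reads at 345 and 360 min, against 1.40% or less in the other late libraries. The proteasome list also lay below other genes (median 0.06, camera adjusted p = 0.00733; adjusted p = 0.746 with an estimated correlation), with an adjusted p of 0.293 without the 3 libraries; camera sets a list against other genes, so it can point down although the median is above 0. Its polyubiquitin gene UBI4 was 3.07-fold higher, while PRE3 and PUP2 differed by 0.35 and 0.34 and were lower by 0.13 and 0.15 with libraries centred.

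**Figure D3:**
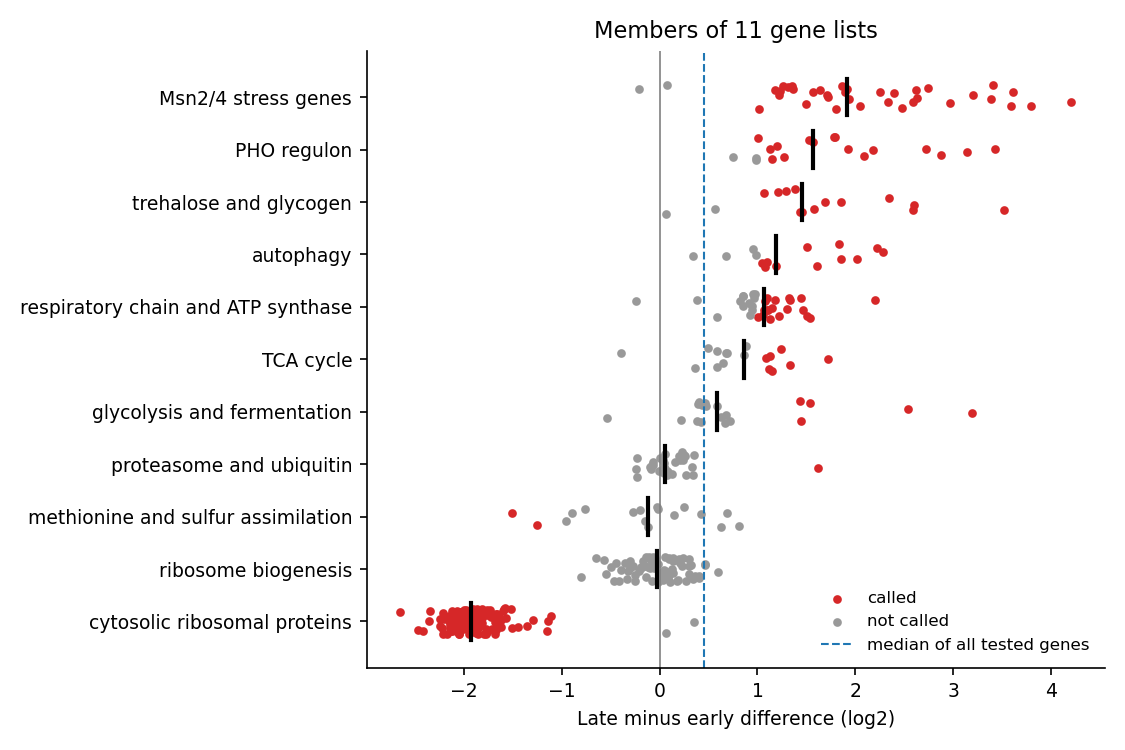
Late minus early difference (log2, x axis) of every tested member of 11 gene lists (y axis); red points were called, grey points were not, black bars are list medians and the dashed line is the median of all tested genes (0.45). Ribosomal protein genes center on -1.93 and stress genes on 1.92.

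Among cell cycle lists, G2/M genes (3 of 17 higher, camera adjusted p = 0.0122; adjusted p = 0.588 with an estimated correlation) included CLB1 (3.48-fold), CDC5 (2.06-fold) and SWI5 (2.04-fold). M/G1 genes (4 of 17 higher, camera adjusted p = 0.00572; adjusted p = 0.588 with an estimated correlation) included PCL9 (3.49-fold), DSE4 (2.79-fold) and ASH1 (2.20-fold). Ergosterol genes (3 of 24 higher, camera adjusted p = 0.0165; adjusted p = 0.588 with an estimated correlation) were led by ERG25 (3.08-fold), ERG11 (2.13-fold) and ERG5 (2.12-fold), and the list was not called with libraries centred (adjusted p = 0.175). CLB1, PCL9 and ERG25 were also called with centring, and CDC5, SWI5, DSE4, ASH1, ERG11 and ERG5 were not. CDC5 fell short of the limit without the 30, 60, 300 or 315 min library (0.98 to 0.99) and SWI5 without the 30, 45, 75 or 315 min library (0.94 to 0.99).

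The largest single increases outside these lists were adjacent genes on the same strand of chromosome XIII. Their levels were alike, and whether they are separate changes was not tested. YMR175W-A (611314 to 611508) was 20.9-fold higher, from 5.24 ± 0.30 to 9.62 ± 1.10, and SIP18 (611016 to 611255), a desiccation-related gene, 18.8-fold higher, from 5.50 ± 0.26 to 9.73 ± 1.05 (SD, n = 8; limma adjusted p = 9.33e-09 and 7.72e-09). The cell wall mannoprotein gene HPF1 was 16.6-fold higher, GRE1 15.1-fold and FMP16 14.7-fold.

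In each list the counts adjusted over the list alone equalled those adjusted over all genes, in all 3 comparisons. With the preset correlation camera called 14 of 25 lists late minus early, 14 middle minus early and 12 late minus middle, and with an estimated one 1, 0 and 0. Fry, which tests whether a list's genes moved on balance one way and makes no comparison with other genes, gave late minus early a false discovery rate of 1.63e-09 for the PHO regulon, 6.52e-08 for stress genes, 6.23e-08 for ribosomal proteins, 0.9 for ribosome biogenesis and 0.292 for the proteasome list.

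By the middle window 196 genes were higher and 122 lower than early. Genes of the PHO regulon and the stress list already stood higher and ribosomal protein genes already lower. With libraries centred, 104 were higher and 158 lower, against a median shift of 0.28. Of the calls, 190 higher and 121 lower genes were also called late minus early. The PHO regulon had 14 of 19 higher (median 1.39, camera adjusted p = 6.46e-11; adjusted p = 0.501 with an estimated correlation). Ribosomal proteins had 117 of 137 lower (median -1.19, camera adjusted p = 1.1e-107; adjusted p = 0.15 with an estimated correlation). Stress genes had 28 of 37 higher (median 1.31, camera adjusted p = 3.31e-07; adjusted p = 0.501 with an estimated correlation), and 17 when scaled to reads outside ribosomal protein genes. Ribosome biogenesis lay below other genes (median -0.45, camera adjusted p = 5.3e-22; adjusted p = 0.501 with an estimated correlation), with 0 of 74 called by limma and 38 lower at an unadjusted p under 0.05. Of the 74, 9 were called lower when scaled to reads outside ribosomal protein genes, 5 with libraries centred and 1 without the 15, 345 and 360 min libraries. The largest called increases were HPF1 (log2 2.70), PHO5 (2.70), GND2 (2.62), GPH1 (2.59) and PHM8 (2.53). The largest decreases were RPS22A (-1.56), RPL8A (-1.56), RPS21B (-1.55), RPL26B (-1.50) and RPS18B (-1.49).

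Between the middle and late windows few genes were called, 31 higher and 4 lower. In this step limma called 0 of 19 PHO regulon genes (8 higher at an unadjusted p under 0.05; median 0.27, camera adjusted p = 0.408), whereas 11 of 37 stress genes were higher (camera adjusted p = 0.000166; adjusted p = 0.762 with an estimated correlation). Ribosomal protein genes lay further below other genes (median -0.74, camera adjusted p = 9.66e-91; adjusted p = 0.159 with an estimated correlation), with 2 of 137 called lower, 134 lower at an unadjusted p under 0.05 and 58 called lower with libraries centred. Respiratory chain genes lay above other genes (median 0.54, camera adjusted p = 4.78e-11; adjusted p = 0.541 with an estimated correlation), with 0 of 33 called by limma and 31 higher at an unadjusted p under 0.05. Ribosome biogenesis lay above other genes (median 0.40, camera adjusted p = 0.0276; adjusted p = 0.919 with an estimated correlation), and the direction turned without the 15, 345 and 360 min libraries (adjusted p = 0.407). YMR175W-A rose by 2.5 (log2, SE 0.44, limma adjusted p = 0.000679), SIP18 by 2.41, GRE1 by 1.94, FMP16 by 1.86 and HSP26 by 1.83. The 4 lower genes were ASC1 (-1.26), a component of the small ribosomal subunit whose gene holds a small nucleolar RNA, SAM2 (-1.19), RPL9A (-1.18) and RPL8A (-1.09). The cell wall gene SPI1 rose by 1.32. In both steps 23 genes were called higher and 2 lower, and 0 changed direction. The count depended on single libraries: it was 23 without the 135 or 150 min library, 53 without 210 min and 58 without 225 min, and 17 higher and 64 lower with libraries centred.

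A spline over the 24 libraries called 1399 of 4343 genes as changing with time, 1200 ending higher and 199 lower. These included 746 of the 747 genes called late minus early. With libraries centred 831 genes were called.

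The timing of the PHO regulon was described by half-rise times, the time at which a gene first reached the level midway (log2) between 0 min and its maximum. They ran from 32.2 min for VTC4 to 165 min for PPN1, a vacuolar polyphosphatase gene, with a median of 86.9 min over 19 genes. The polyphosphate synthesis genes VTC4 (95% interval 22.9 to 40.0 min) and VTC3 (37.5 min), SPL2 (43.0 min) and PHO84 (50.2 min, 46.8 to 54.3) were early. PHO5 (110 min, interval 102 to 120) reached its midpoint 60.3 min after PHO84 (interval 52.1 to 69.7). PHO8 (125 min) and PHM8 (127 min, 118 to 134) were later still. The interval of the difference to PHO5 included 0 for PHO8 and excluded it for PHM8. Residuals around the running median are 0 where values rise steadily, as for PHO84 up to 240 min. All these intervals therefore understate the scatter between libraries, and the order of genes with close times stays open. The total rise was 29.5-fold for PHO5, 23.3-fold for PHO89, 15.4-fold for PHO84 and 2.81-fold for PPN1. The order at the early end rests on the single 0 min library. With a baseline of 0, 15 and 30 min SPL2 was earliest (50 min), followed by VTC3 (56.6 min) and VTC4 (59.2 min), PHO84 moved to 89 min and PHO5 to 117 min, so their gap was smaller than the interval above, and the median was 99.6 min. With libraries centred the median was 58.5 min.

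**Figure D4:**
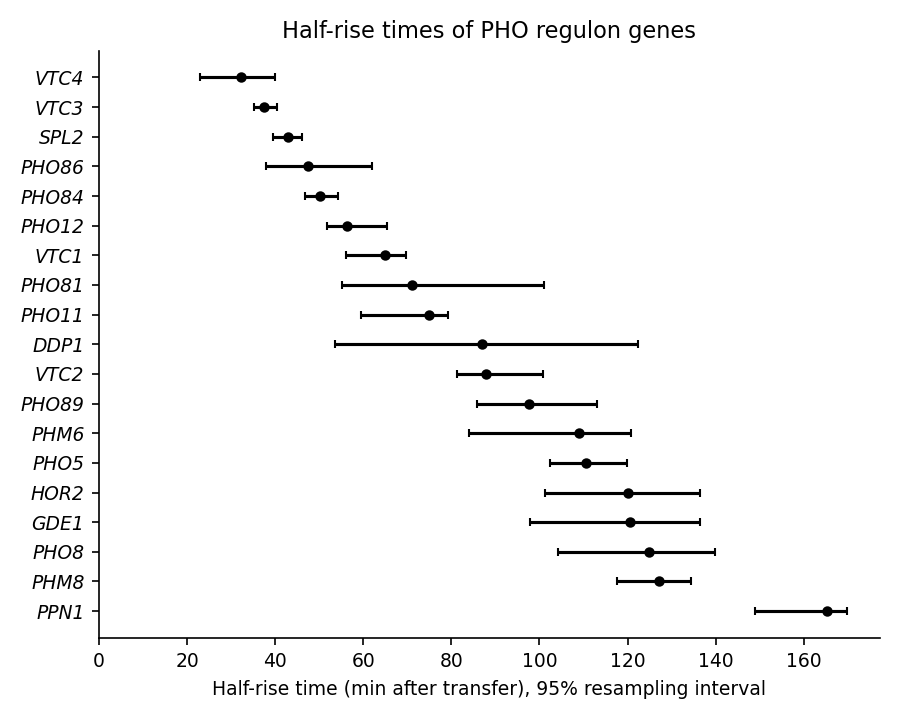
Half-rise time (min after transfer, x axis) of 19 PHO regulon genes (y axis), with 95% intervals from resampled residuals. These intervals understate the scatter between libraries. VTC4 comes first at 32.2 min and PPN1 last at 165 min; with a baseline of 0, 15 and 30 min SPL2 (50 min) comes before VTC4 (59.2 min).

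The single 0 min library allowed no test against the early window, and differences have no replicate check. Of 4360 genes, 90 were at least 2-fold higher in the early median and 17 at least 2-fold lower. Among the 10 largest increases were the PHO regulon genes SPL2 (7.42-fold), VTC4 (4.69-fold), PHO84 (4.69-fold), VTC3 (4.58-fold), PHO11 (4.49-fold) and PHO12 (4.24-fold), and 15 of 19 members were at least 2-fold higher. HSP42 (4.92-fold) and TMA10 (4.05-fold) had 15 reads at 0 min, the floor. The largest decreases were BRN1 (3.12-fold lower), ADA2 (2.67-fold) and the iron permease gene FTR1 (2.62-fold). As a description of these libraries and not a test, since a peculiarity of the 0 min library would move whole lists, list medians were set among 10000 matched random lists. Those of the PHO regulon, of stress genes and of trehalose and glycogen genes exceeded 100% of them, those of methionine and sulfur genes 99.92%, glycolysis 99.91%, the TCA cycle 99.78% and the proteasome list 99.43%, and those of ribosomal proteins and ribosome biogenesis exceeded 0%. Low percentiles were also found for glucose-induced hexose transporters (0.37%, 4 genes), histones (1.59%), the zinc regulon (1.76%) and the iron regulon (2.66%).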

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

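In windows of 8 libraries, a library was set apart when its gap to the nearest other, over the window's range, exceeded Dixon's critical value (95%). Of 427 such windows of library measures, list shares and named genes, 25 were set apart, against about 21.4 by chance (1 in 20), and real change inside a window adds to this. The tests of explanations below were chosen after the results were seen, apart from the counts over other splits of the libraries.

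The 15 min library, the shallowest, was set apart most often. It listed 3450 genes (nearest 4640), its tested genes had a median of 6.44 (nearest 6.01), and it held 0.916% of reads in ribosome biogenesis, 0.811% in the respiratory chain and ATP synthase and 0.649% in purine synthesis. That median leaves out low genes under its floor. Over the 3255 genes listed in all 25 libraries the 15 min median was 6.54, against 6.49 at 30 min and 6.48 at 120 min. The 15 min levels of SYG1 (6.32), NOP1 (7.42), ERG5 (7.19), GCV1 (7.36) and ADE17 (9.34) also lay apart. Other library measures set apart were the 300 min library's 1150000 reads (nearest 792000) and the 135 min library's 4520 listed genes (nearest 4860).

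At 135 min the share of glucose-repressed hexose and gluconeogenic genes was 0.0417% and PAH1 stood at 5.01. At 240 min the share of Gcn4 targets was 1.24%, that of glucose-induced hexose transporters 0.118%, SPB4 stood at 6.60 and HXT3 at 9.02. At 120 min the glucose-induced hexose transporters held 0.1% of reads, and at 45 min methionine and sulfur genes held 0.430%. In the late window PHO89 at 345 min (9.87), DDP1 at 345 min (8.24), SAM1 at 330 min (5.91), GCV1 at 360 min (7.39) and SPI1 at 255 min (6.10) lay apart.

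The first pattern was the general rise of tested genes, a median of 0.45 late minus early. Depth and the floor do not account for it, since genes listed in all 25 libraries rose by a median of 0.38 (95% interval 0.36 to 0.40). A uniform background acting alone is argued against too. Genes in the third of 4 expression bins rose by 2.05 times as many RPM as those in the lowest bin (interval 1.87 to 2.19). A background beside a smaller ribosomal protein share was not tested. Scaled to reads outside the ribosomal protein genes, the other tested genes had a median of 0.005 (interval -0.006 to 0.018), against 0.47 before, which is consistent with the smaller ribosomal protein share. That scaling fixes the total of the other genes, though not their median. A change in RNA per cell was not tested.

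The second pattern was the rise of PHO90. Scaled to reads outside ribosomal protein genes PHO90 was still higher by 0.48 (SE 0.12), so the smaller ribosomal protein share could account for only part of the 0.94. Reads shared with PHO87 and PHO91 are argued against, since their summed late level was 6.49% of the PHO90 rise of 2263 RPM. The biology of the withdrawal itself stays open as an explanation and was not tested separately, since no strain without the overexpression was analysed here. The only high-phosphate library was that of 0 min. Withdrawal and time in culture therefore cannot be told apart, for PHO90 or for any other late minus early change.

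The third pattern was the higher ribosomal protein share at 345 and 360 min (11.2% and 11.1%). Low read totals are argued against, because 315 and 330 min had 493480 and 516423 reads and a mean share 3.38 percentage points lower. Whether these are libraries of earlier time points under a wrong label cannot be told apart from a late change in the cells. Over 3275 genes their nearest library up to 255 min was that of 240 min, with an SD of the log2 difference of 0.364 on average, against 0.539 and 0.482 from the 330 min library, and between the median (0.302) and the highest (0.389) of successive libraries up to 330 min. PHO5 stood in both above every level from 15 to 255 min by 0.32 (scatter around its trend 0.27), and so did the median of 65 ribosome biogenesis genes, by 0.66 at 345 min and 0.31 at 360 min (scatter 0.33), but with libraries centred that median differed by only 0.22 and -0.08 (scatter 0.32), and PHM8 at 360 min (9.25) lay under its 225 min level (9.66).

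Other splits of the libraries bear on each count of genes. Late minus early, 1 of 100 splits of the 16 libraries, the real one, gave 747 genes, and the highest other gave 381. Middle minus early, 1 of 100 gave 318, and the highest other gave 254. Late minus middle, 2 of 100 gave at least 35, and the highest other gave 45, more than the real split. For the time trend, 1 of 100 orders gave 1399, and the highest other gave 890. For all 4 counts the share of arrangements with at least as many genes was under 0.05. Successive libraries of a course are not interchangeable, and a smooth drift over time would favour the real arrangement. The shares therefore do not decide what lay behind the counts. Other splits called up to 381 or 254 genes. Such a split can keep most libraries of a window together and so hold much of the real contrast. Which libraries those splits grouped was not examined.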

How the results depend on the processing

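No paired analysis was possible because there was 1 library per time point and the windows hold different time points. The pseudocount and count-model alternatives were not run, since the values are log2. The minimum of 10 RPM removed 0 tested genes (lowest mean 21.2 RPM), so it tested nothing. Plain limma settings barely moved calls, since every gene past the size limit late minus early had an adjusted p of at most 0.00503. Fits with missing entries at the floor, scaled to reads outside ribosomal protein genes or without the 15, 345 and 360 min libraries were added after the data were seen, as were the alternatives for the 0 min comparison, both of which stayed within 1.5 times the main count. Unless given otherwise, the cause was not tested.

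Late minus early (747 genes, 599 higher) gave 380 genes (181 higher) with centring, 410 (237 higher) with quantile normalization and 392 (201 higher) scaled to reads outside ribosomal protein genes, as those scalings remove the general rise. With no size limit it gave 3089 (2771 higher, 318 lower), and with a limit of 2 it gave 131 (74 higher, 57 lower), by construction. Middle minus early gave 104 higher with centring, 181 (122 higher, 59 lower) with quantile normalization, 300 higher with library weights and 88 higher with scaling to reads outside ribosomal protein genes. Late minus middle gave 81 (17 higher, 64 lower) with centring, 19 higher and 11 lower with quantile normalization, 20 higher and 21 lower with the ribosomal protein scaling, and 18 lower without the 3 libraries. The time trend gave 831 genes with centring and 846 with quantile normalization. The median half-rise time was 99.6 min with the longer baseline and 58.5 min with centring, where PPN1 rose too little to count.

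Leaving out each library gave 711 to 782 genes late minus early (563 to 633 higher, 147 to 152 lower), 277 to 385 middle minus early (179 to 245 higher, 98 to 140 lower), 23 to 58 late minus middle (20 to 43 higher, 3 to 15 lower) and 1319 to 1506 for the trend.

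With an estimated correlation 1 list was called late minus early and 0 in each of the other comparisons, against 14, 14 and 12 with the preset one. Late minus middle, ribosome biogenesis changed direction without the 3 libraries (adjusted p = 0.407) and glycolysis with quantile normalization (adjusted p = 0.727). For the named genes, most values over the alternatives came from fits that left out 1 library. The 10 RPM minimum and the plain limma settings could not move a difference. A high share of unchanged values was therefore largely fixed in advance. Over 120 named genes and their alternatives, 4039 of 4199 values kept their direction and side of the limit, 97 fell below it, 45 passed it and 18 changed direction. None of the genes behind those 18 was called late minus early. With centring they were PHO91 (-0.21), FTH1 (-0.013), ISU2 (-0.071), HXT3 (-0.19), PRE3 (-0.13) and PUP2 (-0.15). With quantile normalization they were PHO91 (-0.20), FTH1 (-0.041), ISU2 (-0.008), STD1 (-0.074), STE3 (-0.089), ZIP1 (-0.14) and DIT1 (-0.052). With the ribosomal protein scaling they were PHO91 (-0.18), ISU2 (-0.048), HXT3 (-0.17), PRE3 (-0.11) and PUP2 (-0.13). Genes under 15 reads in a library had no value there, which limits low genes most in the shallow late libraries. Missing low genes also raise the median on which a shallow library was centred for the gene tests.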

Other observations

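Other lists did not stand apart from the rest of the genes late minus early by camera, although some members of several passed the limits for a call. On the deposited scale they moved up as groups, as the median of all genes did: fry, which makes no comparison with other genes, gave a false discovery rate of 2.46e-07 for cell wall integrity (median 0.74), 4.16e-07 for the zinc regulon (median 0.60), 9.37e-07 for Gcn4 targets (median 0.44), 2.75e-06 for G1/S genes (median 0.50), 3.6e-05 for purine synthesis (median 0.42), 0.000175 for histones (median 0.59), 0.00061 for the iron regulon (median 0.34) and 0.0032 for phospholipid synthesis (median 0.36). With libraries centred on their median this direction was lost or turned for the iron regulon (median -0.21), phospholipid synthesis (-0.12), purine synthesis (-0.07), Gcn4 targets (-0.06) and G1/S genes (0.003), and the medians of cell wall integrity (0.25), the zinc regulon (0.11) and histones (0.10) were smaller. Gcn4 targets of amino acid synthesis had 4 of 44 members higher (camera adjusted p = 0.814), among them GLN1 at 2.35-fold and CPA1 at 2.31-fold. Purine synthesis had 3 of 20 higher (adjusted p = 0.823), MTD1, GCV1 and ADE17, and cell wall integrity 6 of 18 (adjusted p = 0.253), led by GSC2 (4.45-fold), SPI1 (3.72-fold) and PST1 (3.04-fold). Phospholipid synthesis had 1 of 17 (adjusted p = 0.372), the phosphatidate phosphatase gene PAH1 (2.03-fold), which fell short of the limit without the 60, 75, 90, 300, 315, 330 or 360 min library (0.93 to 0.997), with PCT1 at 0.84 and EKI1 at 0.73 not called. The zinc regulon had 1 of 11 (adjusted p = 0.372), ZAP1 itself (2.97-fold), with ADH4 at 0.88 and IZH1 at 0.86 not called. The iron regulon had 0 of 13 (adjusted p = 0.485, FIT3 at 0.77; 7 higher at an unadjusted p under 0.05), G1/S genes 0 of 31 (adjusted p = 0.372, with PCL1 at 0.94, or 1.01 and 1.00 and called without the 45 or 330 min library, TOF1 at 0.85 and CLN1 at 0.82; 26 higher at an unadjusted p under 0.05) and histones 0 of 10 (adjusted p = 0.426, with HHF1 at 0.92, HHT1 at 0.87 and HTZ1 at 0.71; 7 higher at an unadjusted p under 0.05). Glucose-repressed genes had 1 of 6 higher (adjusted p = 0.787), the hexose transporter gene HXT7 (5.14-fold), which is nearly identical to HXT6, while ICL1 (0.84) and HXT2 (0.57) were not called. Glucose-induced hexose transporters had 0 of 4 called (3 higher at an unadjusted p under 0.05), and of 3 sporulation genes NDT80 was 2.16-fold higher, short of the limit without the 60 min library (0.98). All of these counts are from limma. With libraries centred, and likewise with scaling to reads outside ribosomal protein genes, Gcn4 targets had 0 higher and 2 lower, purine synthesis 1 higher and 2 lower, and cell wall integrity 3 higher and 1 lower. With libraries centred, GLN1 (0.74), PAH1 (0.48) and NDT80 (0.56) were not called.

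Of the genes deleted in BY4741, HIS3, LEU2 and MET17 had a value in 0 of 25 libraries, whereas URA3 had one in 2. Of the MATa-specific genes 0 of 6 were called (adjusted p = 0.823; limma had 4 higher at an unadjusted p under 0.05), with STE2 at 9.04 ± 0.17 late (SD, n = 8). The single tested MATalpha-specific gene, STE3, stood at 5.27 ± 0.33 (SD) over the late libraries that listed it. The lowest late share of the MATalpha list was 0%, so some late libraries had no value for STE3. Mitochondrially encoded genes had 0 tested members.

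Of genes without a value in any early library, 8 had one in all 8 late libraries, and 1 gene, MMP1, went the other way, at least 1.63-fold lower than in the early libraries. They were chosen after their values were seen: TKL2 was at least 9.65-fold, YBR116C at least 9.55-fold, HXT5 at least 6.96-fold, MOH1 at least 5.33-fold and RRT1 at least 5.18-fold higher than the mean early floor of 13.2 RPM, and GIT1, TPO2 and YDR034W-B were the rest. These may not all be separate changes. MOH1 (126828 to 127244) and RRT1 (127299 to 127610) are neighbours on the same strand of chromosome II, at 70.6 and 68.6 RPM late. TKL2 and YBR116C had like late levels (127.7 and 126.4 RPM). YBR116C had no position in the annotation used here, so an overlap was not checked.

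The share of reads in the stress list was 0.433% at 0 min, 1.25% at 15 min, 0.702% at 90 min and 5.47% at 330 min, and it stood at 3.74% at 225 min, 2.76% at 240 min and 3.50% at 345 min. The early rise rests on the single 0 min library and was highest in the 15 min library, the shallowest. Whether it was a separate phase was not tested. After 210 min the ribosomal protein share was above that of the library before at 225, 240, 255, 315 and 345 min; the stress share was then lower than before at 240, 315 and 345 min and higher at 225 and 255 min.

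The order of the groups was tested on list medians, the first of these tests being chosen after the result was seen. The PHO regulon may have changed before the ribosomal protein genes: their half-change times were 81.8 and 176 min, 94.2 min apart (95% interval 82.6 to 105). This order rests on the 0 min baseline, since with a baseline of 75, 90 and 105 min the times were 181 and 179 min. A hypothesis written beforehand was that stress genes rose when ribosomal protein genes fell. Stress genes reached their midpoint earlier, at 158 min, a difference of -18.1 min (interval -24.3 to -7.7). With the later baseline it was at 164 min, against 179 min for ribosomal protein genes, and no interval was computed. Both gaps are close to the spacing of the libraries, and the first rests on the 0 min baseline. The intervals given here came from residuals around a running median and understate the scatter between libraries. The test therefore cannot decide whether the changes coincided. From 135 to 210 min the ribosomal protein median fell from 10.81 to 9.07, while the stress median rose from 6.75 to 8.67 (log2).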
